A study of Mus musculus with 8 samples.

How the data were processed

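The series profiled chromatin in CD140b+ cells, which carry the PDGF receptor beta, taken from mouse lungs at postnatal day 7 by magnetic sorting. H3K4me2, a histone mark of promoters and enhancers, was profiled by CUTAC, a variant of CUT&Tag in which the antibody-tethered Tn5 transposase cleaves mostly accessible DNA next to marked nucleosomes. It was run in 2 control (Ctrl) and 2 Foxf2 knockout (KO) libraries, and FOXF2 itself was profiled by CUT&Tag in 2 wild-type libraries. The knockout joins a floxed Foxf2 allele with an inducible Cre under Pdgfrb control, per the labels. A further 2 wild-type IgG libraries are not used here. Nothing in the labels states whether replicates of a group came from separate animals. SDs and the permutation test of peak number therefore cover the spread between these libraries, which may be technical. All other p-values take regions or genes as units and do not measure the spread between libraries.

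Per the submitters' processing notes, the tools were Trim Galore, Bowtie2, MACS2 and deepTools and the genome build was mm10. Their versions, settings and order, the use of a control library in peak calling and the peak threshold are not given in the sources used here. The deposited files are peak lists per library, not pooled over replicates. Each peak has its interval, its summit and 4 values made by the authors. The first of the deposited values is a fold enrichment, a ratio that the authors' peak caller gives over its background. The deposited lists also give the −log10 p-value and the −log10 q-value at the summit. The deposited score is 10 times the −log10 q-value in the H3K4me2 lists and 10 times the −log10 p-value in the FOXF2 lists. The lowest −log10 q-value was between 1.30 and 1.33 in the H3K4me2 lists, and the lowest −log10 p-value was 5.01 in both FOXF2 lists, so the thresholds of the marks differed. These values are the authors' own for each peak and were used to describe, rank and filter peaks within a list. They were not compared directly between lists, but summit pileups inferred from them were, in the alternatives matched on depth or signal and in the closing section.

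Peaks on chromosomes 1 to 19, X and Y were kept, which left out between 3 and 37 peaks per list on other contigs. The H3K4me2 lists were merged into 61479 regions where intervals shared 1 bp or more, and a library was counted as present in a region where its peaks covered 1 bp or more. A control-only region had a peak in both Ctrl libraries and in neither KO library, and a knockout-only region the converse. Peaks of the 2 FOXF2 libraries that shared 1 bp or more were merged into reproducible FOXF2 peaks. Strength was the rank percentile of the −log10 p-value within a list, taken as the mean of both Ctrl lists for strata and as the lower of both lists for naming genes.

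Gene positions came from a RefSeq gene table of the same assembly (GRCm38.p6, 21883 protein-coding genes). It gives gene starts and ends with neither strand nor exons, so the planned promoter class became a window of 1 kb around either annotated gene boundary, and the rest was divided into inside a gene and intergenic. The planned test of the forkhead motif needs a genome sequence and was not run. A region was given to the gene with the nearest boundary within 100 kb, which names a neighbour and not a target.

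The difference in peak number was tested by an exact permutation test, two-sided. The share of FOXF2 peaks in Ctrl regions was set against 1000 circular shifts along each chromosome, one-sided. Among regions with a peak in both Ctrl libraries, the odds of having no KO peak with against without a FOXF2 peak were compared by a Cochran-Mantel-Haenszel odds ratio over 10 strata of Ctrl strength, each divided by gene boundary, with a bootstrap over 5 Mb blocks (1000 resamples). Such regions are not replicates, and these tests cover the regions of these libraries, not animals. For 21 gene lists with 448 entries, all matched in the gene table, the odds of a control-only region were compared in the same way over strength deciles, and the share of genes with a FOXF2 peak was compared with other genes that had a boundary peak in both Ctrl libraries (Fisher's exact test, two-sided). Both used Benjamini-Hochberg adjustment over lists. The planned stratified test did not suit 24 knockout-only regions, and 10000 draws within strength deciles took its place. That replacement was made after the planned test had called the epithelial list from 1 region. The odds ratio of loss was first computed with strength deciles alone, and the planned strata with gene boundary were restored after both values had been seen. The lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes Foxf2 and Pdgfrb, the 10 genes with the strongest FOXF2 peak at a gene boundary and away from one, the 10 with the strongest control-only, knockout-only and FOXF2-bearing control-only region, and up to 4 members of each list. Of the genes this rule takes, 1 is not reported here.

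Read depth is unknown from the lists themselves. For every peak but a few in FOXF2 replicate 1, where 99.98% gave a solution, the fold enrichment and p-value together fixed a whole-number summit pileup and a background under the caller's Poisson model (tolerance 0.002 on the −log10 scale). The lowest background, the shortest peak as fragment length and an assumed effective genome of 1.87 Gb gave an estimated 11.5 and 13.1 M fragments in the Ctrl libraries, 9.97 and 9.74 M in the KO libraries, and 14.2 and 15.5 M in the FOXF2 libraries. These depths rest on that inference. The alternatives matched on depth or signal, and the pileup tests of the closing section, used the inferred pileups and backgrounds rather than these fragment numbers.

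Alternatives were −log10 q-values of at least 5 or 10, lists limited to the length of the shortest, 500 bp summit windows, overlap of at least 50%, sex chromosomes left out, other strata, other distances to genes, replicate numbers as a block and each library left out in turn. Alternatives matched on depth or signal, and some strata, were added after seeing the data. The functions were tested on simulated data. All of 2000 simulated pileups were recovered, and 100 simulations of loss over 36602 regions at true odds ratios of 0.5, 1 and 2 gave median estimates of 0.498, 1.01 and 2.01, with the true value inside the 95% interval in 91, 94 and 98 of them. The simulations of loss used strata of strength alone and drew each region independently. They held no difference in strength or width within a decile, so they do not test the reported interval against such differences. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.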

Results

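Pericytes wrap lung capillaries and depend on signals exchanged with endothelial cells, and FOXF2 is a forkhead transcription factor of the vascular mesenchyme. The libraries described here locate FOXF2 on the genome of sorted CD140b+ lung cells at postnatal day 7 and compare their H3K4me2-marked chromatin with and without Foxf2. H3K4me2 peaks numbered 55370 and 46908 in the 2 Ctrl libraries and 25035 and 32515 in the 2 Foxf2 KO libraries. The 2 wild-type FOXF2 libraries held 28510 and 21504 peaks. Estimated depth ranged from 9.74 to 15.5 M fragments per library.

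The Foxf2 gene (mm10, chromosome 13, 31625816 to 31631406) carried an H3K4me2 peak at or within 1 kb of its lower-coordinate boundary in all 4 H3K4me2 libraries, the knockouts included. Within the gene and 1 kb around it, there were 2 H3K4me2 peaks in each Ctrl library, 1 in KO replicate 1 and 3 in KO replicate 2. The labels do not name the deleted part of the floxed allele, and a peak outside it checks nothing, so the marks at this gene neither support nor contradict the genotype labels. FOXF2 peaks were found at both ends of its own gene. One spanned 31624228 to 31626087 in replicate 1 and 31624335 to 31626082 in replicate 2. Another lay just past the higher-coordinate end, at 31631783 to 31632884 in replicate 1 (97.9th percentile of that list) and 31631838 to 31632789 in replicate 2 (98.4th percentile). Pdgfrb, which encodes the receptor used for the sort (chromosome 18, 61045127 to 61085067), carried an H3K4me2 peak at its lower-coordinate boundary in all 4 libraries. Within its own list that peak stood at percentile 50.6 in Ctrl 1, 70.0 in Ctrl 2, 13.3 in KO 1 and 82.8 in KO 2. The KO libraries thus lay on either side of both Ctrl libraries there. Inside the Pdgfrb gene, H3K4me2 peaks between 61054437 and 61057495 were listed in both Ctrl libraries and in neither KO library. They were weak to moderate, at the 9.45th and 22.1st percentiles in Ctrl 1 and between 2.46 and 50.3 in Ctrl 2. That stretch overlapped the gene's strongest FOXF2 peaks, at 61056377 to 61059872 in replicate 1 (99.3rd percentile) and 61056359 to 61057651 in replicate 2 (95.3rd percentile).

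**Figure D1:**
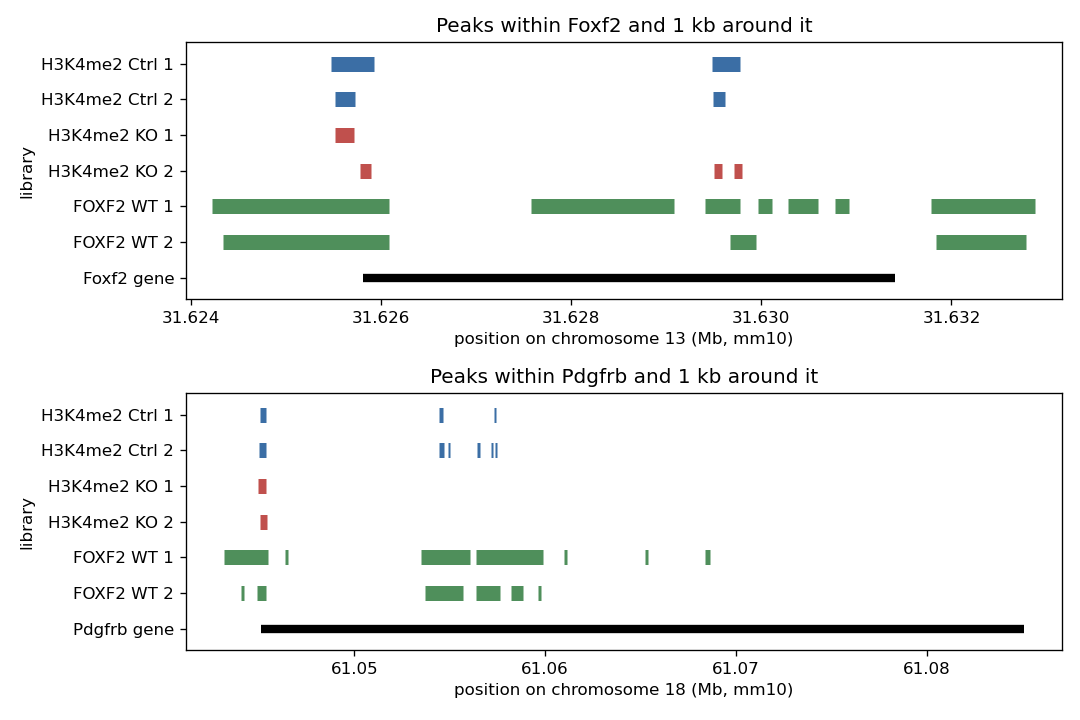
Peaks of each library (horizontal bars) within Foxf2 and Pdgfrb and 1 kb around them, against mm10 position in Mb, with the gene as a black bar. FOXF2 peaks flank Foxf2 and overlap the part of the Pdgfrb gene body where only the Ctrl libraries have H3K4me2 peaks inside the gene. Every H3K4me2 library has a peak at the lower-coordinate boundary of Pdgfrb.

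Where FOXF2 sits in these cells was asked of the peaks shared by both FOXF2 libraries. The strongest of these at a gene boundary lay at Cltc (clathrin heavy chain; chromosome 11, 86756645 to 86758623), Kmt5b, which methylates histone H4 (chromosome 19, 3767112 to 3769881), Tle4 (chromosome 19, 14597984 to 14599397), Calm3 and Zswim6. They were followed by Ubb, Tbx2, Hsp90ab1, Snrnp70 and Tle3. Tle3 and Tle4 encode Groucho-type corepressors, and Tbx2 is a T-box factor of lung mesenchyme. Away from gene boundaries, the strongest lay inside Pdzrn3 (chromosome 6, 101374173 to 101375731), 27180 bp from Gpbp1, and 17766 bp from Fos (chromosome 12, 85454739 to 85456124). Others were nearest to A430057M04Rik, Adamts10, Prdm6, a repressor known from smooth muscle, Ror1, which binds WNT5A, Nmnat2, and Axin2, a feedback inhibitor of WNT signalling. Ranked by the lower of the percentiles in both lists, these peaks lay between 99.8 and 99.98.

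In all, 14252 FOXF2 peaks were reproducible, which took up 51.1% of the list of replicate 1 and 72.3% of that of replicate 2. Of these, 70.0% overlapped a region with H3K4me2 in both Ctrl libraries. Over 1000 circular shifts the mean was 1.81% and the highest value 2.39% (permutation by shifts, one-sided p = 0.001, the smallest these can give). Both assays cut DNA with tethered Tn5, and the shifts were not limited to accessible DNA. Overlap above them therefore does not separate FOXF2 binding from background cutting at accessible chromatin, and no IgG library was compared. Regions called FOXF2-bound below are those that hold a reproducible FOXF2 peak. A gene boundary lay within 1 kb of 40.5% of the reproducible FOXF2 peaks, a further 32.4% were inside a gene and 27.1% were intergenic. That boundary share was slightly below the 42.8% of Ctrl H3K4me2 regions (odds ratio 0.907, Fisher's exact test, two-sided p = 1.31e-06). Of the reproducible FOXF2 peaks, 2849 (20.0%) overlapped no H3K4me2 peak of any library, and 4.88% of those lay at a gene boundary. The number of reproducible peaks fell to 6603 at a −log10 q-value of at least 10 and to 8761 with a reciprocal overlap of 50%.

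FOXF2 peaks were most frequent at genes of the immediate early response and of TGF-beta and BMP signalling. Of 19 immediate early genes with H3K4me2 at a boundary in both Ctrl libraries, 18 had a reproducible FOXF2 peak within 1 kb, against 46.6% of other such genes (odds ratio 20.6, Fisher's exact test, adjusted p = 3.79e-04). Fos, Jun, Dusp1 and Jund had the strongest peaks of this list, with 8, 4, 7 and 3 reproducible peaks nearest to them. Of 27 genes of the TGF-beta and BMP pathway, 21 had a FOXF2 peak at a boundary (odds ratio 4.00, Fisher's exact test, adjusted p = 0.0159), among them Tgfbr3, the TGF-beta co-receptor betaglycan, with 11 peaks, the ligand gene Tgfb1 with 4, Ltbp2 with 7 and the signal transducer Smad3 with 8. Housekeeping genes came next, at 9 of 12 genes (75.0%, odds ratio 3.43, Fisher's exact test, adjusted p = 0.275), and did not pass. Against all protein-coding genes their odds ratio was 5.58 (Fisher's exact test, adjusted p = 0.0122), so a high share was not particular to signalling or response genes. Endothelial markers had fewer, at 2 of 17 genes (11.8%, odds ratio 0.152, Fisher's exact test, adjusted p = 0.0222). That endothelial difference was not called without FOXF2 replicate 1, where 2 lists passed in place of 3, nor against all protein-coding genes (odds ratio 0.275, Fisher's exact test, adjusted p = 0.166), nor within strata of Ctrl boundary strength (Cochran-Mantel-Haenszel odds ratio 0.472, adjusted p = 0.340, n = 17 genes). The immediate early and the TGF-beta lists passed in each of these. Without FOXF2 replicate 2 the odds ratios were 10.3 for immediate early genes, 7.16 for the TGF-beta list and 0.238 for endothelial markers, and all 3 passed.

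When each FOXF2 peak was given to its nearest gene within 100 kb, 5 of 21 lists passed. Some lists share genes, so these calls are not independent. Tgfb1, Tgfb2, Tgfb3, Tgfbr1, Tgfbr2, Tgfbr3, Eng, Acvrl1 and Bmp4 stand in both the pericyte-endothelial signalling and the TGF-beta lists. Notch3, Jag1 and Dll4 stand in both the signalling and the Notch lists. No list was tested without its shared genes. The TGF-beta and BMP pathway had a peak at 25 of 27 genes, immediate early genes at 18 of 19, extracellular matrix and basement membrane genes at 27 of 31, Notch pathway genes at 15 of 18 and pericyte-endothelial signalling genes at 29 of 40, against 50.0% of other marked genes (Fisher's exact test, adjusted p from 1.16e-04 to 0.0315). In the signalling list the strongest peaks were nearest to Tgfbr3, the endothelin receptor gene Ednra, Tgfb1 and Tgfb2. Matrix genes were led by Eln, Lama5, Col4a1 and Col4a2, which encode elastin, a laminin chain and collagen IV chains, and Notch genes by Hes1, Notch2, Rbpj and Notch1. These names were taken from the whole lists. Tgfb2 and Rbpj had no boundary peak in either Ctrl library and so were not among the genes tested. Among pericyte markers, Gucy1a1 and Gucy1b1, the subunits of the nitric oxide receptor, had peaks at the 99.6th and 99.1st percentiles, and Pde5a had 8 peaks, but the list of 27 genes did not pass (19 genes, odds ratio 2.38, Fisher's exact test, adjusted p = 0.109). It passed without FOXF2 replicate 1 (odds ratio 8.71, Fisher's exact test, adjusted p = 0.00163) and against all protein-coding genes (odds ratio 4.20, adjusted p = 7.26e-04). None of the 21 lists passed within strata of the number of Ctrl H3K4me2 regions per gene, where a Cochran-Mantel-Haenszel test gave 3 an unadjusted p below 0.05. Endothelial markers had fewer genes with a peak there (odds ratio 0.208), and the TGF-beta and matrix lists had more (odds ratios 4.57 and 3.34). Leaving out FOXF2 replicate 2 ended the calls of the Notch and the signalling lists, and leaving out replicate 1 ended none of the 5.

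**Figure D2:**
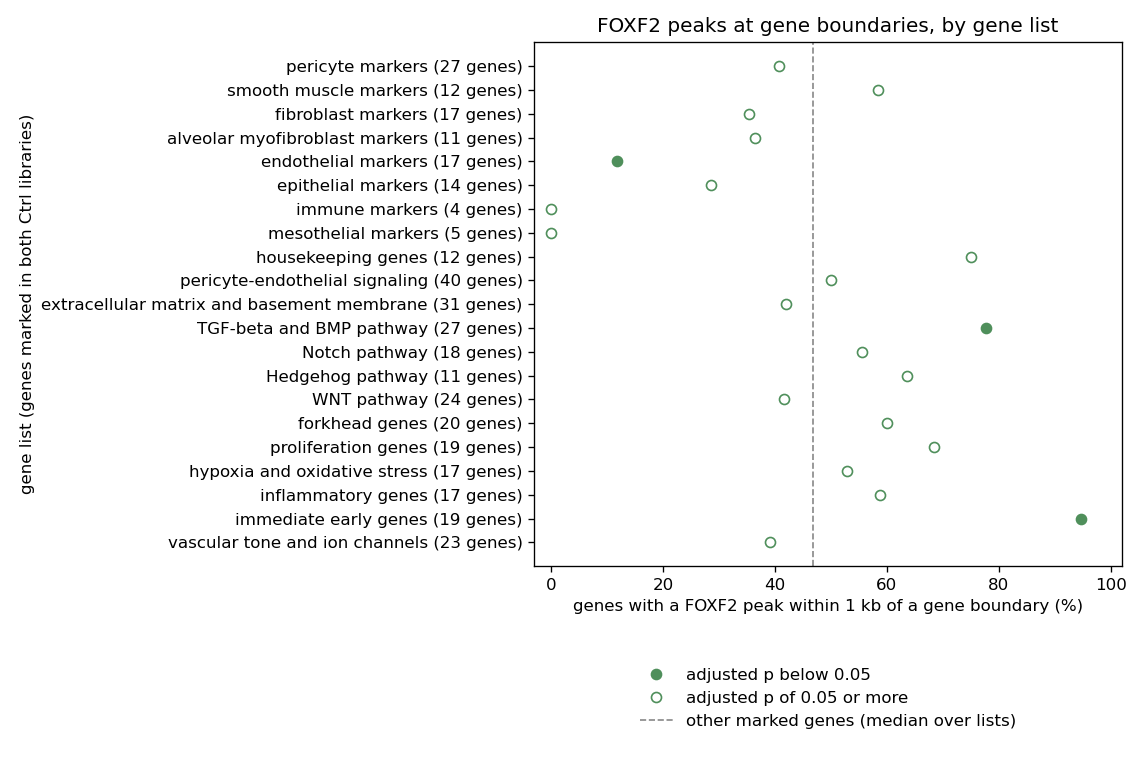
Share of genes (%) with a reproducible FOXF2 peak within 1 kb of a gene boundary, for each of 21 gene lists (rows), among genes with H3K4me2 at a boundary in both Ctrl libraries, with filled points for an adjusted p below 0.05 and a dashed line for other marked genes. Immediate early genes (18 of 19) and the TGF-beta and BMP pathway (21 of 27) lie to the right of the line, and endothelial markers (2 of 17) to its left.

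H3K4me2 in the Foxf2 knockout was compared with that of littermate controls to find chromatin that differed without the factor. Both knockout libraries listed fewer peaks than either control library, and the regions they lacked were mostly away from gene boundaries and weak, at a median Ctrl percentile of 33.5 against 81.0 for regions found in all 4 libraries. Ctrl libraries held 51139 ± 5984 peaks (SD, n = 2) and KO libraries 28775 ± 5289 (SD, n = 2), a ratio of 1.78, covering 17.2 ± 0.171 Mb and 9.64 ± 0.381 Mb. Both Ctrl values lay above both KO values, and the exact permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. Of 61479 merged regions, 19068 had a peak in all 4 libraries, 10940 were control-only and 24 knockout-only. The other ways to divide the 4 libraries into pairs gave 181 and 521 regions (Ctrl 1 with KO 1 against Ctrl 2 with KO 2) and 853 and 219 (Ctrl 1 with KO 2 against Ctrl 2 with KO 1). A gene boundary lay within 1 kb of 65.0% of the regions found in all 4 libraries and of 15.1% of control-only regions (odds ratio 0.0957, Fisher's exact test, p below 1e-300). That share was also low in the other classes, at 16.7% of knockout-only regions and 15.4% of regions with any other pattern. The count of control-only regions fell to 1426, against 270 knockout-only, when all lists were limited to equal length, and to 1796 when Ctrl signal was scaled to that of the KO libraries. It rose to 19272 without Ctrl replicate 1 and to 25674 without Ctrl replicate 2. Knockout-only regions rose to 72 and 101 without Ctrl replicates 1 and 2, and to 1750 and 447 without KO replicates 1 and 2.

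**Figure D3:**
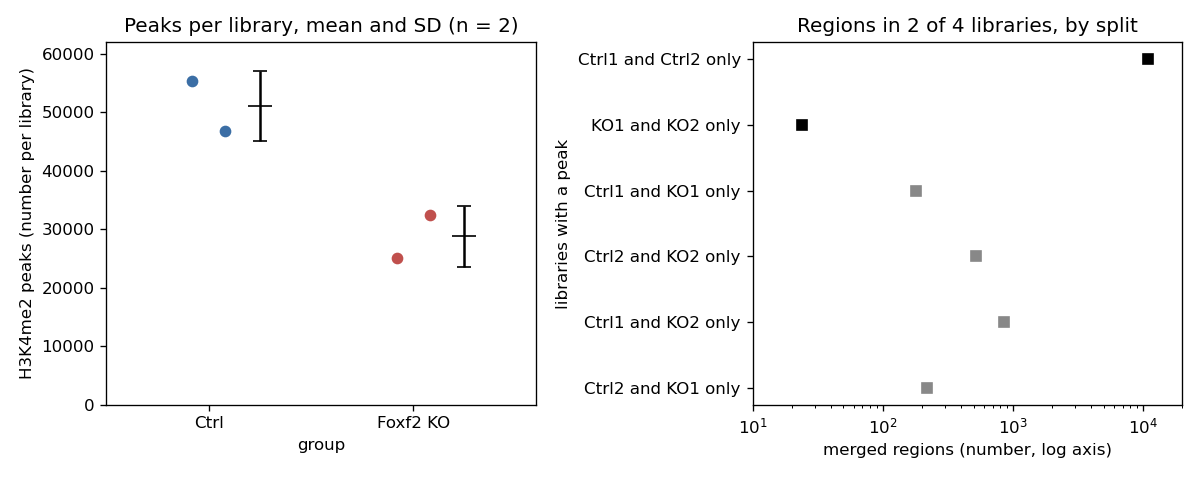
Left, H3K4me2 peaks per library (points) with mean and SD (n = 2) for each group; right, merged regions with a peak in exactly 2 of the 4 libraries on a log axis, the Ctrl and KO pairs in black and the other pairings in grey. Both Ctrl libraries lie above both KO libraries, and control-only regions number 10940 against 24 knockout-only.

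The strongest control-only regions were at or near Gap43, a growth cone protein gene (chromosome 16, 42339677 to 42339840, inside the gene and 811 bp from its boundary), Gm50595 (chromosome 2, 75609477 to 75609874), Cdc26, a subunit of the anaphase-promoting complex (chromosome 4, 62407746 to 62408088), the lysophosphatidic acid receptor gene Lpar3 (59092 bp away), Krtap28-13 and Mbd2. Irf2, Cstad, Svop and Ccdc102a completed the 10. Their strength was moderate, between 71.2 and 74.0 by the lower of their percentiles in both Ctrl lists. The knockout-only regions were weak, the strongest being 29504 bp from Zfp706 at the 17.7th percentile (chromosome 15, 36967354 to 36967523). Mark2, Tmem125, Prpf40b, Tmcc1, Phf2, Rbms2, Fli1, an ETS factor of endothelial and blood cells, Dtx1, a regulator of Notch signalling, and Prickle1 followed, at the 11.5th percentile or below. Of the 24 regions, 18 had a gene boundary within 100 kb.

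Of 20 endothelial genes, 18 had a boundary peak in each Ctrl library, 9 in KO replicate 1 and 10 in KO replicate 2. Of the 17 marked in both Ctrl libraries, Aplnr, Cdh5, Emcn, Gpihbp1 and Plvap had none in either knockout library. Genes of equal Ctrl strength gave 2.38 such losses on average (95% range 0 to 5), so these 5 did not pass (permutation within strength deciles, one-sided p = 0.0510 over 10000 draws, adjusted p = 1). Of 29 pericyte markers, 27 and 28 had a boundary peak in the Ctrl libraries and 24 and 25 in the KO libraries. Smooth muscle genes numbered 13, 12, 12 and 13 of 16 in Ctrl 1, Ctrl 2, KO 1 and KO 2, fibroblast genes 18, 18, 13 and 18 of 21, alveolar myofibroblast genes 11, 11, 10 and 10 of 12, and housekeeping genes 12, 12, 11 and 11 of 13. Markers of cells that the sort should leave out also had boundary peaks, with epithelial genes at 18, 14, 11 and 16 of 20, mesothelial genes at 6, 5, 1 and 4 of 8 and immune genes at 5, 5, 3 and 5 of 20. A peak within 1 kb of a gene end may belong to a neighbouring gene. Sftpc, for one, was counted in every library, but no region of both Ctrl libraries was nearest to it. These counts therefore do not show that such cells were present.

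**Figure D4:**
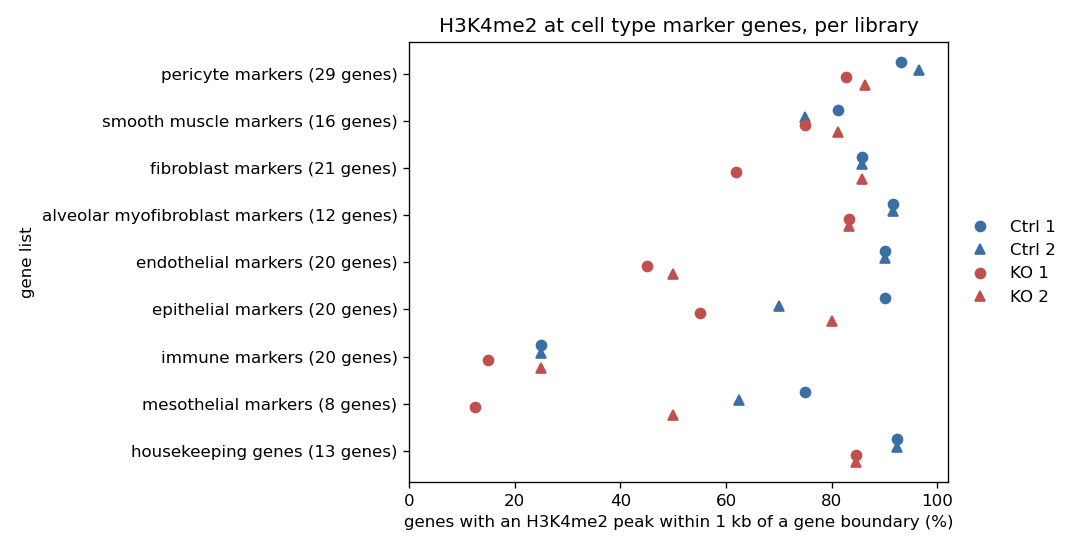
Share of genes (%) with an H3K4me2 peak within 1 kb of a gene boundary, for 9 marker and housekeeping lists (rows), with a point for each Ctrl (blue) and KO (red) library. Endothelial markers show 18 and 18 of 20 genes in the Ctrl libraries and 9 and 10 in the KO libraries.

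Among all regions of listed genes, none of the 21 lists differed from other regions in the odds of being control-only at equal Ctrl strength after Benjamini-Hochberg adjustment of the Cochran-Mantel-Haenszel test, and 4 had an unadjusted p below 0.05. In these tests n counts regions, which are not replicates. Alveolar myofibroblast markers had 23 regions control-only (n = 42 regions, odds ratio 2.95, 95% interval 1.21 to 7.20, adjusted p = 0.104), with the strongest near Lgr5, Tgfbi, Wnt5a and Aspn. The Notch pathway had 45 (n = 103 regions, odds ratio 1.94, 1.13 to 3.32, adjusted p = 0.104), led by Notch4, Notch1, Nrarp and Dll1. Fibroblast markers had 22 (n = 86 regions, odds ratio 0.476, 0.268 to 0.848, adjusted p = 0.104), Col1a1 and Pi16 first, and epithelial markers 9 (n = 41 regions, odds ratio 0.352, 0.138 to 0.897, adjusted p = 0.166). Regions of pericyte markers, such as those near Cox4i2 and Notch3, were control-only in 33 cases (n = 86, adjusted p = 0.362). Those of pericyte-endothelial signalling genes, Tgfb2, Fgf2 and Flt1 among them, were so in 73 (n = 197, adjusted p = 0.825), and those of extracellular matrix genes, led by Lama4 and Nid2, in 56 (n = 141, adjusted p = 0.812). Without KO replicate 2 the odds ratios were 0.949 for epithelial, 1.51 for alveolar myofibroblast and 0.790 for fibroblast markers, and without Ctrl replicate 2 that of epithelial markers was 0.582. For the Notch pathway it was 1.46 without KO replicate 2 and 1.87 without KO replicate 1. Without Ctrl replicates 1 and 2 the Notch odds ratio was 1.63 and 1.51. With lists of equal length, endothelial markers passed, with 11 regions control-only (31.4%, n = 35 regions) against 6.48% of others (odds ratio 3.87, adjusted p = 0.00967). Fibroblast markers passed without Ctrl replicate 2 (n = 123 regions, odds ratio 0.490, adjusted p = 0.0399) and the Notch pathway with signal-matched Ctrl lists, chosen after seeing the data (n = 55 regions, odds ratio 3.79, adjusted p = 0.0241). Only 1 listed gene, Nkx2-1, a lung epithelial factor, had a knockout-only region, and no list passed (0 had an unadjusted p below 0.05; lowest permutation p = 0.0768 over 10000 draws).

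The remaining lists had adjusted p-values between 0.212 and 0.936. Control-only regions made up 24 of 71 for proliferation genes (Ccnd2 and Cdk6 first), 13 of 52 for the Hedgehog pathway (Gli3, Ptch1), 46 of 122 for the WNT pathway (Dkk2, Sfrp2), 61 of 167 for the TGF-beta and BMP pathway (Tgfb2, Ltbp4) and 40 of 103 for forkhead genes (Foxk1, Foxp4). They made up 28 of 75 for vascular tone and ion channels (Pde3a, Itpr1), 11 of 62 for hypoxia and oxidative stress (Hif1a, Epas1), 25 of 75 for inflammatory genes (Nfkbia, Relb), 34 of 111 for immediate early genes (Dusp1, Klf6), 20 of 51 for smooth muscle markers (Smtn, Ldb3) and 40 of 88 for endothelial markers (Egfl7, Cdh5). Mesothelial, immune and housekeeping lists had 5 of 8, 3 of 14 and 10 of 39.

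Whether regions with a FOXF2 peak lost H3K4me2 more often was asked of the 36602 regions marked in both Ctrl libraries. Of these, 11651 held a reproducible FOXF2 peak. Loss was less frequent there: 17.4% of regions with a FOXF2 peak and 35.7% of regions without one had no peak in either KO library. Part of this gap followed strength, since 82.3% of regions in the weakest decile and none in the 3 strongest were lost, and FOXF2 peaks were in 17.6% of the former decile and 59.3% of the strongest. Without strata the odds ratio was 0.380, and at equal strength and boundary class it was 0.843 (95% interval 0.781 to 0.911, Cochran-Mantel-Haenszel p = 1.69e-05, n = 36602 regions, which are not replicates; 0.785 to 0.908 over 530 blocks). The 3 strongest deciles, with no loss, add nothing to the value at equal strength, although the n given here and below counts them. They held 1645, 2107 and 2170 of the FOXF2-bound regions. The odds ratio at equal strength rested on KO replicate 1: without that library, with regions merged anew from the other lists, it was 1.00 (95% interval 0.929 to 1.08). It also ended when region width was added to the strata (0.944, p = 0.166, n = 36602 regions). The odds ratio was 0.518 in Ctrl 1 with KO 1 alone and 0.476 with deciles of fold enrichment. FOXF2-bearing regions that were lost, 2032 in all, were led by those near Cdc26, Cdc42ep1 (chromosome 15, 78832334 to 78833126), Srr, where the region lies inside Smg6, Smtn, the smooth muscle gene of smoothelin (chromosome 11, 3573164 to 3573532), Epb41l2, and Nfat5, an osmotic stress factor. Rapgef5, the laminin gene Lama4 (chromosome 10, 38908368 to 38908612), Znhit6 and Tmem184b followed.

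**Figure D5:**
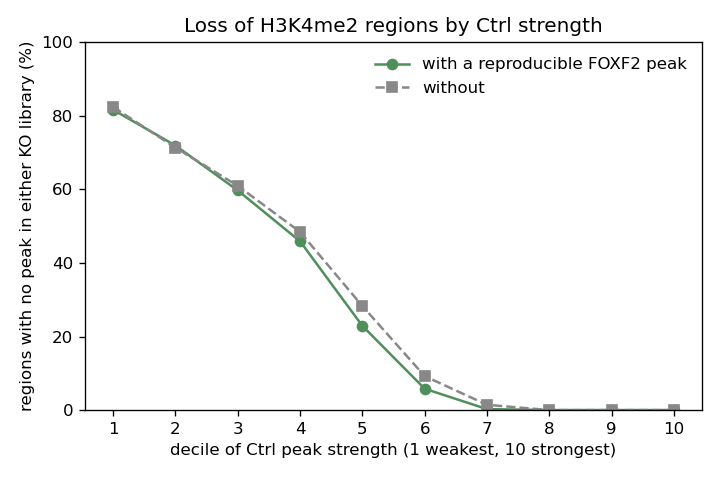
Share of H3K4me2 regions of both Ctrl libraries (%) with no peak in either KO library, by decile of Ctrl strength, for regions with (green) and without (grey) a reproducible FOXF2 peak. Loss falls from 82.3% of all regions in decile 1 to none in deciles 8 to 10, and the 2 lines lie close together, at 22.9% and 28.3% in decile 5.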

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

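Tests matched on depth or signal, on strength alone and on strata for the FOXF2 gene lists were chosen after the results were seen, and all other alternatives were planned. Over the main results, 48 alternative values kept their direction and their side of the threshold or stayed within the allowed range, 24 moved, 2 no longer passed and 1 reversed. The excess of peaks in Ctrl libraries, the share of FOXF2 peaks in Ctrl regions and the location of FOXF2 peaks were in the first set under every alternative run. For the excess of peaks this speaks of direction alone, since 2 against 2 libraries fix its p: it was 22364 as deposited, 14969 and 8622 at −log10 q-values of at least 5 and 10, and 18133 to 26595 with 1 library left out. Control-only regions numbered 4688 at a −log10 q-value of at least 10, 1426 with lists of equal length, 1796 with signal-matched Ctrl lists and 12923 to 25674 with 1 library left out. Knockout-only regions numbered 3 and 2 at −log10 q-values of at least 5 and 10, 270 with lists of equal length, 165 with 500 bp summit windows and 72 to 1750 with 1 library left out. Fewer libraries needed for a call raise both counts by construction, and equal length removes the weakest Ctrl peaks. Reproducible FOXF2 peaks numbered 6603 at a −log10 q-value of at least 10, 8761 with a reciprocal overlap of 50% and 21504 to 28510 with 1 library left out, which then counts every peak of the other. The odds ratio of loss at FOXF2-bound regions was 0.944 with region width in the strata, 0.974 in Ctrl 2 with KO 2 alone, 0.518 in Ctrl 1 with KO 1 alone, 0.476 with deciles of fold enrichment, 0.380 without strata and 0.649 to 1.00 with 1 library left out, the last without KO replicate 1; the cause was not tested. Gene lists with a difference in control-only regions numbered 1 with equal length (endothelial), 1 with signal matching (Notch, odds ratio 3.79) and 0 to 1 with 1 library left out (fibroblast, odds ratio 0.490, without Ctrl replicate 2). Lists that differed in FOXF2 peaks nearest to their genes numbered 18 against all protein-coding genes, 17 with more and 1, immune markers, with fewer, and 0 within strata of Ctrl regions per gene. Lists that differed in FOXF2 peaks within 1 kb numbered 6 against all genes, of which immune markers had fewer (0 of 20 genes), and 2 to 5 with 1 library left out. The 2, without FOXF2 replicate 1, had more, and of the 5, without replicate 2, endothelial and mesothelial markers had fewer. Within strata of Ctrl boundary strength 4 lists had more, the immediate early, TGF-beta, forkhead and pericyte-endothelial signalling lists, the last with an odds ratio of 2.42. The signalling list shares genes with the TGF-beta list and was not tested without them.

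With the replicate number as a block the odds ratio of loss was 0.716, and the call did not change. The labels do not say that equal numbers share an animal or a day, and the deviations of Ctrl and KO replicate 1 from their group means correlated at −0.0496 over 19068 regions, so the pairing rests on the number alone. The forkhead motif tests and their alternatives were not run. Exons and introns were not separated, and gene boundaries stood in for transcription start sites. Estimated depth was 1.24 times higher in the Ctrl libraries, and a weak peak missing from a KO list was not detectable there at this depth rather than shown to be absent.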

Other observations

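Several forkhead and mesenchymal regulator genes had more than 1 FOXF2 peak nearest to them. Foxf1, the closest relative of Foxf2, was nearest to 5 reproducible FOXF2 peaks, the strongest at the 98.9th percentile, and Foxf2 to 4. Forkhead genes as a list did not pass for FOXF2 peaks within 1 kb (12 of 20 genes, Fisher's exact test, adjusted p = 0.622) and passed within strata of Ctrl boundary strength, chosen after seeing the data (odds ratio 3.09, adjusted p = 0.0292, n = 20 genes). Across all protein-coding genes, Rbpms, an RNA-binding protein gene, had the most with 16, followed by Fancc and Tns1 with 15 each and Filip1l and Irf2bp2 with 14 each. The T-box gene Tbx5 had 11, the Hedgehog receptor gene Ptch1 had 9 and Axin2 had 7. Rbpms, Fancc, Tns1, Filip1l and Irf2bp2 were chosen after their values were seen, and these counts were not tested against gene length.

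Tests of fewer endothelial cells and of loss specific to FOXF2-bound regions, the calibration between replicates, and all comparisons of recovered pileup between libraries were chosen after the results were seen; the other tests were set before. Summit pileups here are inferred from each peak's fold enrichment and p-value. At the 19068 regions called in all 4 libraries, the median pileup over background was 70.0 and 66.4 in the Ctrl and 34.9 and 46.9 in the KO libraries. The median log2 difference was −0.71, with lower KO values in 99.4% of regions. Before division by background, median pileups were 36 and 39 in the Ctrl libraries and 21 in both KO libraries. The gap between the KO libraries thus enters with the background. The shortest peak, taken as fragment length, was 113 bp in KO 1 and 84 to 86 bp in the other H3K4me2 libraries, which raises the background of KO 1. These regions are a selected set that leaves out regions missing from any library.

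The first pattern is the excess of control-only regions, and 10092 of 10940 were left after Ctrl lists were scaled to the inferred KO backgrounds. That scaling held no sampling noise. The background of KO 1 (0.602) was above those of Ctrl 1 and Ctrl 2 (0.515 and 0.587), so the scaling raised Ctrl pileups for KO 1. It therefore cannot set aside fewer fragments in the KO libraries as a cause. One uniform drop in signal with Poisson noise gave 4089 expected regions, 37.4% of those seen, and regions nearly sure to be called were missed 26.0 times as often as chance gives (25 against 0.960), which by the limits set beforehand would have counted against a uniform drop and for region-specific effects. Those limits were wrong for these data, because the same model between replicates of 1 group also gave too few missing regions (2.80 to 3.79 times as many seen) and too few sure ones (9.36 to 30.6 times), so both readings were changed to open after the values were seen. Across groups the shortfall was unlike that between replicates, at no more than 1.77 times from a Ctrl to a KO library (sure regions 0.778 to 3.15 times) and 14.8 to 23.2 times from a KO to a Ctrl library (sure regions 145 to 210 times). A uniformly lower signal, which may be technical, and an effect of the knockout at particular regions therefore cannot be told apart, as the counting model falls short even where no knockout is involved.

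The second pattern is the lower odds of loss at FOXF2-bound regions. A candidate explanation is that FOXF2 peaks mark regions that are kept better between any libraries: regions with a FOXF2 peak were also less often missing between the Ctrl libraries (odds ratios 0.398 and 0.898) and between the KO libraries (0.890 and 0.490). Values below 1 thus arise with no knockout involved, so the limit of 1 set for a preferential loss where FOXF2 was bound was wrong for the odds ratio of 0.843, which was 1.00 without KO replicate 1 and 0.944 with region width in the strata. From single Ctrl to single KO libraries the odds ratios were 0.518, 0.771, 0.670 and 0.974, the last above all 4 values between replicates and the others among them, so a preferential loss and none cannot be told apart. Pileup at FOXF2-bound regions (n = 8241 regions) differed from the Ctrl values by a median log2 of −0.69, against −0.71 for random regions (random sets of equal strength, two-sided p = 0.002, the smallest that 1000 draws give).

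The third pattern concerns endothelial markers, which were examined in 4 ways. Their control-only regions did not pass (40 of them, n = 88 regions, adjusted p = 0.308), they passed with lists of equal length (odds ratio 3.87, adjusted p = 0.00967), and the loss of 5 boundary peaks lay within the range of 0 to 5 of genes with equally weak Ctrl peaks (adjusted p = 1). At regions of 13 endothelial genes called in all 4 libraries, the median log2 pileup difference was −0.97, against −0.75 for random regions (−0.88 to −0.63; random sets of equal strength, n = 21 regions, adjusted p = 0.0160 over 20 lists, the only one to pass), lowest at Tie1 (−1.59) and Tal1 (−1.46), and inside the random range for KO 1 against Ctrl 1 alone (6.08th percentile). Some of these regions lie close together at the same gene, as at Esam and Vwf, while the random sets drew single regions. The random range may therefore be too narrow, and regions are not replicates. Ctrl peak strength could account for the lost calls, though the lost boundary peaks lay between the 19.4th (Emcn) and the 63.0th (Cdh5) percentile. Fewer endothelial cells among the sorted cells of the KO libraries might account for the lower pileup, a hypothesis found and tested on the same data. A change within endothelial cells was not tested, and of other cells that the sort should leave out, immune markers had −0.73 (random range −0.96 to −0.52) and epithelial markers −0.61 (n = 18 regions, adjusted p = 0.429), which joins −1.17 and −1.04 for KO 1 against Ctrl 1 and Ctrl 2, close to the endothelial −1.12 and −1.11, with −0.28 and −0.31 for KO 2, where endothelial markers had −0.80 and −0.73.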
